A study of Homo sapiens with 15 samples.

How the data were processed

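RNA was measured by sequencing in 15 libraries of 2 human breast cancer cell lines, MCF-7 and T47D, in 8 groups of cell line and medium. Per the labels' protocols, cells grew in DMEM with 10% serum, total RNA was taken with an RNeasy kit and libraries were made with the TruSeq Stranded mRNA kit. The submitters' processing notes name bcl2fastq, kallisto 0.46.1, DESeq2 1.28.1 and the genome build GRCh38, without the role or order of each. The annotation release is not given in the sources used here.

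The authors deposited a table of FPKM for 40182 genes with 1 column for each of the 15 libraries. Of these genes, 11518 were listed at 0 in all 15 libraries. The authors also deposited estimated counts and TPM per transcript for 13 libraries, in the format of kallisto, per the file headers. The other 2 libraries, replicate 1 of MCF-7 in high glucose and replicate 1 of T47D in low glucose, entered through the FPKM table alone. In each of the 13 libraries, TPM summed per gene were proportional to the deposited FPKM within 2% for at least 97.1% of genes. How FPKM was made is not given in the sources used here.

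Columns were matched to libraries by cell line, glucose, dose and number in the column name. For 1 MCF-7 library, replicate 2 at 25 mM BHB, the title states 25 mM and the characteristics field 10 mM. The title was followed, since the series' design text says that only the MCF-7 group at 10 mM lost a library. The column header of the deposited FPKM gives 25 mM for it as well. Gene names, types and coordinates came from GENCODE 29 on GRCh38, which held 35502 of the gene identifiers (88.35%).

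Total estimated counts ran from 18.5 M to 35.5 M in the 13 libraries. For the other 2, depth was read from the steps between low FPKM values, at 31.5 M for MCF-7 and 20.7 M for T47D. Depth does not enter limma's test on FPKM, and values near the filter rest on few reads.

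Each comparison was tested with limma 3.58.1 (R 4.3.3) on log2(FPKM + 1), with 1 mean per group, empirical Bayes moderation with a trend, and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p below 0.05. Genes needed an FPKM of at least 1 in at least 2 libraries, which left 15447. All 15 libraries shared 1 estimate of the spread per gene, since no group had more than 2, with 7 residual degrees of freedom and 3.99 prior degrees of freedom. Log2 fold changes on the log2(FPKM + 1) scale understate the change of genes with low values. Normalised values led the test because a test on counts would leave 1 reference group per cell line, MCF-7 in high glucose and T47D in low glucose, with a single library. Nothing in the labels says that the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

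The comparisons were low against high glucose, 10 mM and 25 mM BHB against none in low glucose, each within a line and as the mean of both lines, 25 against 10 mM BHB, and the differences between the lines in the glucose and 25 mM BHB responses. The design, the naming rule for genes, 36 gene lists and most alternatives were fixed before the data were examined. Named genes were the 10 with the largest change in each direction (5 for differences between the lines) among called genes whose groups did not overlap, with a mean of at least 5 FPKM in the higher group and a named symbol at an identifier in GENCODE 29, a condition added to the rule after the data were in hand. Added to these were 25 genes named in every comparison and up to 4 called members with the smallest adjusted p per list. Where no gene met the rule, the 5 genes of smallest p with a named symbol at an identifier in GENCODE 29 were named. For these no minimum FPKM was set and groups could overlap.

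Lists with at least 5 measured members, 34 in number, were tested with camera (limma) at a preset inter-gene correlation of 0.01, which compares a list with all other genes, and adjusted over the lists of a comparison. The test was repeated with an estimated correlation. Fry asked whether a list's genes moved, on balance, one way. Of the lists not tested, the list of nuclear-retained RNAs had 0 measured members and the list of blood and endothelial markers had 4.

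Alternatives were another pseudocount, no filter and a filter of 5 FPKM, median-of-ratios scaling, quantile normalisation, a fit on only the libraries compared, no variance trend, the conflicting library set to 10 mM, a series taken from sample numbers as a block, limma on TPM of the 13 libraries, and leaving out each library in turn. Limma on TPM thus had 1 library each for MCF-7 in high glucose and T47D in low glucose, so its calls differ by lost libraries as well as by unit. Estimated counts were summed per gene and rounded for edgeR 4.0.16 (quasi-likelihood test, TMM, its own count filter), edgeR with the size factors of DESeq2, edgeR without a filter, and DESeq2 1.42.0, each on the 13 libraries. Adjusted p-values that DESeq2 gave as missing were left out. Chosen after the data were seen were edgeR on 15 libraries with the counts of 2 rebuilt from FPKM, a fit on genes with at least 10 mean estimated counts, a fit on protein-coding genes, and the agreement between lines without 1 library that stood apart.

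The code for each test was first tested on simulated counts with 66 or 67 genes changed at each of 3 sizes, drawn from the libraries' means, depths and dispersions. For MCF-7 low against high glucose, limma on the simulated FPKM recovered 10.4% of 1.5-fold, 61.2% of 2-fold and 89.4% of 4-fold changes, among 13964 genes with 3 false calls. For T47D these shares were 16.4%, 70.1% and 92.4% among 13932 genes with 5 false calls. For 25 mM BHB they were 29.9%, 79.1% and 92.4% in MCF-7 among 13909 genes with 18 false calls, and 22.7%, 70.1% and 95.5% in T47D among 13920 genes with 9 false calls. Over both lines at 25 mM BHB they were 62.7%, 80.6% and 95.5% among 13935 genes with 14 false calls. These 25 mM BHB comparisons thus held more false calls than the threshold aims at. Over the called genes, the correlation of the BHB and glucose fold changes was also simulated 200 times per line with no BHB effect, a test added after the values were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.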

Results

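Messenger RNA was sequenced from MCF-7 and T47D, 2 human breast cancer cell lines that carry the estrogen receptor, after 4 days in medium with 0.225 g/l glucose (low) or 4.5 g/l glucose (high). Low-glucose cells also received 0, 10 or 25 mM beta-hydroxybutyrate (BHB), a ketone body that cells can oxidise. Each of the 8 groups had 2 libraries, except MCF-7 at 10 mM BHB with 1. Total estimated counts were 18.5 M to 35.5 M in the 13 libraries that had them. Values are FPKM, given as mean ± SD with n = 2 unless stated. Log2 fold changes are on the log2(FPKM + 1) scale with their standard error, and adjusted p-values are from limma unless another tool is named. Coordinates are gene bounds on GRCh38.

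The cell line was the main source of variation. The first principal component held 84.6% of the variance and separated the lines, and the second held 6.0% and placed T47D in high glucose apart from the other T47D libraries. Replicates correlated across genes at 0.990 to 0.992 in every group but MCF-7 at 25 mM BHB, where r was 0.978. Replicate 1 of that group had 9.05% of its counts in mitochondrially encoded genes, against 2.94% to 5.45% in the other 12 libraries with counts.

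**Figure D1:**
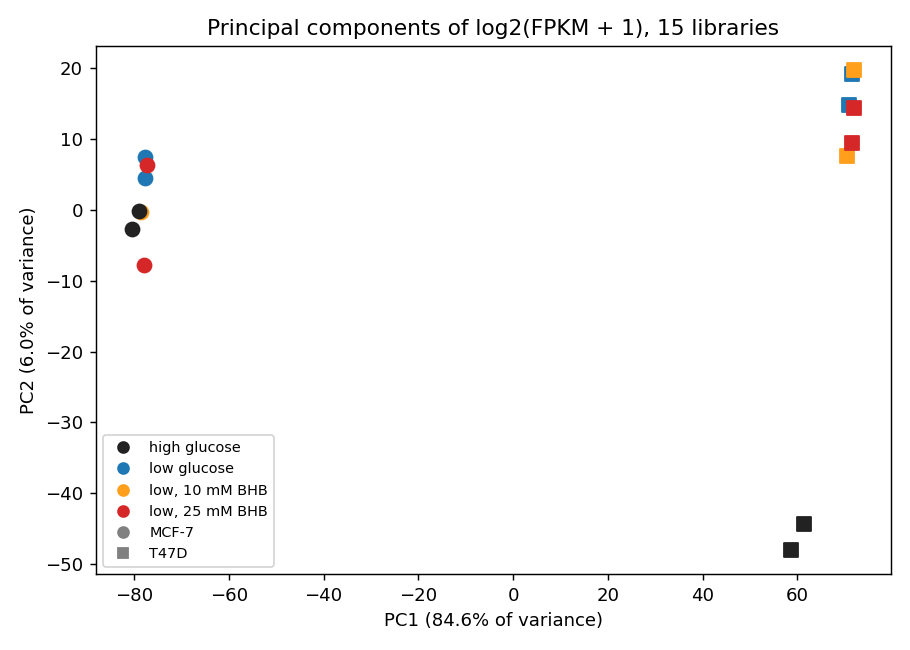
Principal components of log2(FPKM + 1) in the 15 libraries, with the first component on the x axis and the second on the y axis, and 1 point per library coloured by medium. The first component (84.6% of variance) separates MCF-7 from T47D, and the second (6.0%) sets the T47D high-glucose libraries apart.

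The first question was how MCF-7 cells differ between low and high glucose. In low glucose MCF-7 had less TXNIP, a glucose-induced brake on glucose uptake, and less of its relative ARRDC4. TXNIP was at 6.44 ± 1.13 FPKM in low and 104 ± 28.7 in high glucose (log2 fold change −3.79 ± 0.23, adjusted p = 6.71e-05), and ARRDC4 was at 2.26 ± 0.10 in low glucose, 20.6% of its mean in high glucose (−1.87 ± 0.14, adjusted p = 0.000363). Asparagine synthetase, ASNS, rose 2.55-fold from 26.0 ± 0.44 to 66.2 ± 5.4 (adjusted p = 0.000446), and the stress-induced NUPR1 rose from 1.21 ± 0.38 to 7.86 ± 1.10 (adjusted p = 0.000422). TXNIP lies on chromosome 1 at 145992435 to 145996600, ARRDC4 on chromosome 15 at 97960698 to 97973838, ASNS on chromosome 7 at 97852118 to 97872542 and NUPR1 on chromosome 16 at 28532708 to 28539174.

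In all, 14 genes were called in MCF-7, 9 higher and 5 lower, of which 11 were protein-coding. Higher with smaller changes were VEGFA, an angiogenic growth factor (log2 fold change 0.95), CBS of the transsulfuration pathway (0.95), the transferrin receptor TFRC (0.77), the fatty acid-activating enzyme ACSL1 (0.70) and the mitochondrial folate enzyme MTHFD2 (0.60), and NT5E was lower (−0.87). The other called genes, singled out after their values were seen, were NDUFA4L2 (1.44), the 5S rRNA pseudogene RNA5SP61 (1.79), AP001052.1 (−1.70) and AL157834.3 (−1.66). At an unadjusted p below 0.05 there were 876 genes, where chance alone would give 772 in this and every other comparison. Some BHB comparisons had fewer than 772, so this value is no firm reference for chance. The edgeR test on counts called 4 genes, TXNIP, ARRDC4, NUPR1 and ASNS, which also stayed called whichever library was left out. A fit on the MCF-7 glucose libraries alone called 1 gene, in which NUPR1 (adjusted p = 0.346), ASNS (0.106) and ARRDC4 (0.134) missed the threshold. The count was 8 without replicate 1 in low glucose, 43 without either MCF-7 library at 25 mM BHB, and 27 with the library of 2 stated doses at 10 mM. It was 37 with the replicate block, 39 in DESeq2, 53 with no filter, 128 in edgeR without a filter and 9 in limma on TPM. VEGFA missed the threshold without low-glucose replicate 1 (adjusted p = 0.172) or high-glucose replicate 1 (0.116) or 2 (0.0844), and TFRC without low-glucose replicate 1 (0.101) or 2 (0.0714) or high-glucose replicate 1 (0.0863). CBS, ACSL1, MTHFD2 and NT5E lost their calls without any 1 T47D library (adjusted p = 0.0513 to 0.102) or any 1 of the 4 MCF-7 glucose libraries (0.111 to 0.442), except that MTHFD2 kept its call without low-glucose replicate 2.

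Several gene groups fixed in advance lay above or below the other genes in MCF-7. Of 28 measured targets of ATF4, the transcription factor of the integrated stress response, 4 were higher, 0 lower and 24 did not pass (17 higher when adjusted over the list alone), with ASNS, NUPR1, CBS and MTHFD2 among them. Their median log2 fold change was 0.59 and the camera adjusted p was 1.83e-26, with an adjusted p of 0.0567 at an estimated correlation. All 24 genes of cholesterol biosynthesis had positive values (median 0.45). None was called over all genes (edgeR called 0), 15 were higher when adjusted over the list alone, and the camera adjusted p was 1.80e-24 (0.0567 at an estimated correlation). All 25 genes of the unfolded protein response, which handles misfolded protein in the endoplasmic reticulum, were positive as well (median 0.28, 4 higher adjusted over the list alone), with an adjusted p of 2.96e-12, or 0.183 at an estimated correlation. Interferon-stimulated genes were lower as a list of 24 (median −0.46, 10 lower adjusted over the list alone, adjusted p = 2.03e-12), with an adjusted p of 0.0977 at an estimated correlation.

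Camera called 15 of 34 lists in MCF-7 and 0 at an estimated correlation, while fry called 5. The other 11 had medians between −0.19 and 0.18. DNA replication (median −0.18, 0 of 34 called by limma or edgeR), mitosis (−0.19, 0 of 30) and heat shock (−0.10, 0 of 15) were lower, with adjusted p of 0.629, 0.775 and 0.584 at an estimated correlation. Of 11 MondoA targets 2 were lower, TXNIP and ARRDC4 (median −0.02, estimated-correlation adjusted p = 0.0977). Ribosomal proteins (0.18, 0 of 55), autophagy and lysosome (0.17, 0 of 29), fatty acid synthesis (0.16, 0 of 15), hypoxia targets (0.12, 1 of 19), ketone body genes (0.10, 0 of 10), serine and one-carbon synthesis (0.07, 1 of 20) and the nuclear-encoded respiratory chain (0.06, 0 of 60) were higher. Their adjusted p at an estimated correlation were 0.403, 0.266, 0.0567, 0.0567, 0.211, 0.403 and 0.784 in that order. Adjusted over the list alone, 2 autophagy, 1 fatty acid synthesis, 1 hypoxia, 3 ketone body and 2 serine genes were higher. Mitosis lost its call without high-glucose replicate 2 (median −0.10), ketone bodies and heat shock without high-glucose replicate 1 (0.09 and 0.01) or low-glucose replicate 2 (0.05 and −0.01), the respiratory chain without replicate 1 of low (0.00) or high glucose (0.01), and MondoA targets without either 25 mM library (−0.02).

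**Figure D2:**
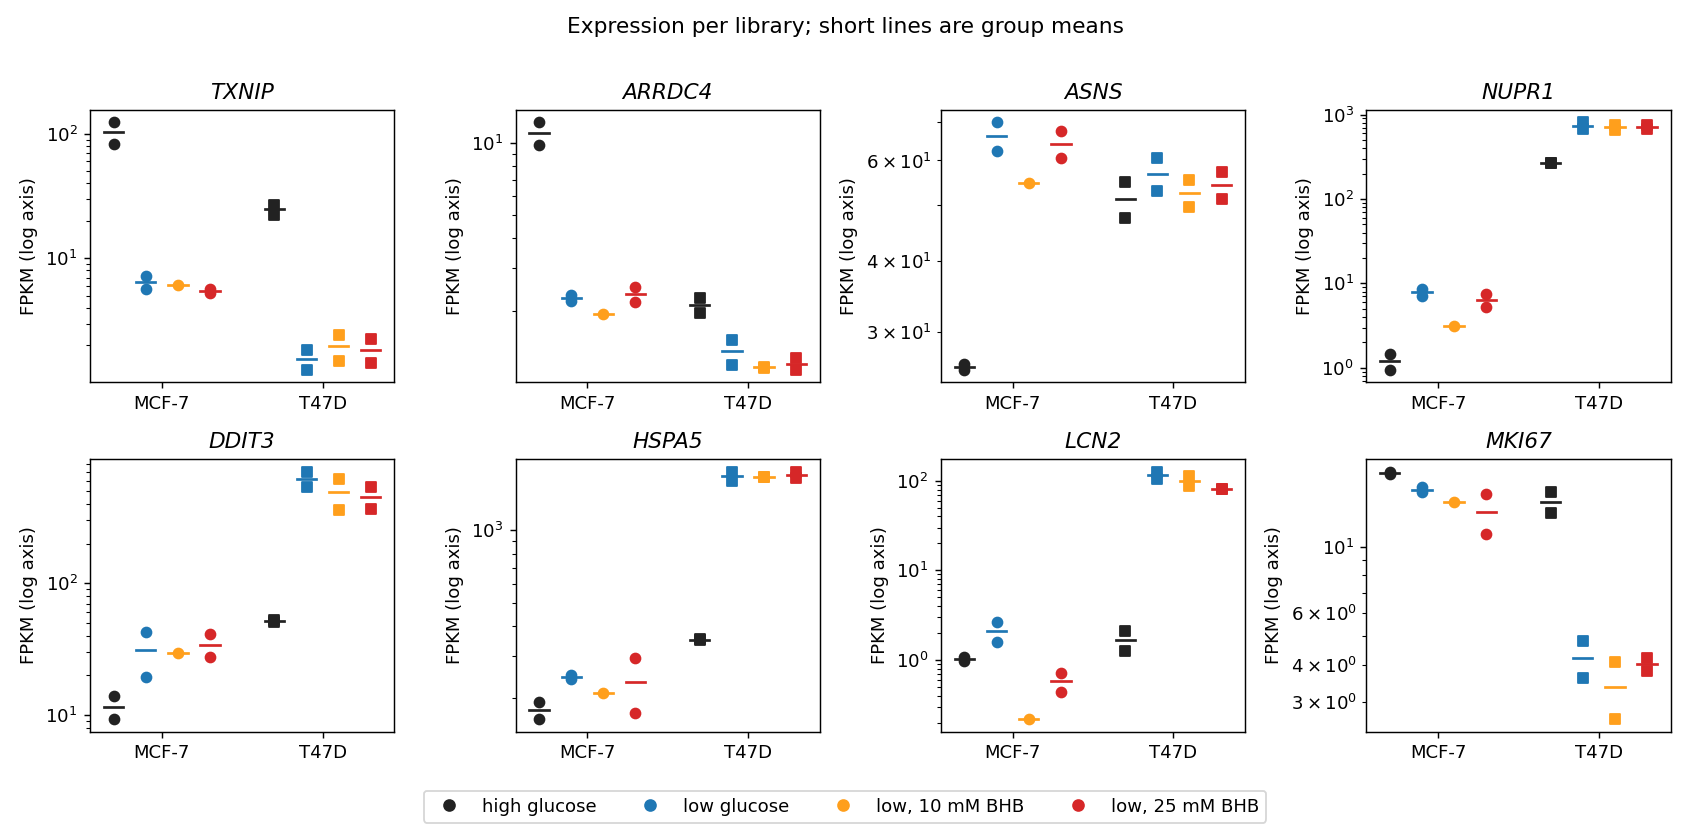
FPKM of TXNIP, ARRDC4, ASNS, NUPR1, DDIT3, HSPA5, LCN2 and MKI67, 1 panel per gene, on a log axis, with 1 point per library by cell line and medium and short lines at group means. TXNIP is low in every low-glucose group of both lines, whereas DDIT3, HSPA5 and LCN2 are high in T47D in low glucose, where LCN2 reaches 116 FPKM against 1.68 in high glucose.

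The same question in T47D gave a much wider response. In low glucose LCN2, an iron-carrying secreted protein, rose 69.1-fold, from 1.68 ± 0.60 to 116 ± 14.9 FPKM (log2 fold change 5.46 ± 0.21, adjusted p = 3.85e-07). The stress factor DDIT3 (CHOP) rose 11.9-fold from 52.0 ± 1.38 to 620 ± 119 (3.54 ± 0.37, adjusted p = 6.45e-05), and HSPA5, the main chaperone of the endoplasmic reticulum, 4.80-fold from 350 ± 1.16 to 1683 ± 107 (2.26 ± 0.19, adjusted p = 1.88e-05). TXNIP fell from 24.7 ± 3.15 to 1.56 ± 0.41 (adjusted p = 1.30e-05) and RRM2, a subunit of the enzyme that makes deoxyribonucleotides, from 125 ± 12.7 to 18.4 ± 6.20 (−2.73 ± 0.26, adjusted p = 4.15e-05). LCN2 lies on chromosome 9 at 128149071 to 128153455, DDIT3 on chromosome 12 at 57516588 to 57521737 and RRM2 on chromosome 2 at 10120698 to 10131419.

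Called in T47D were 3798 genes, 1892 higher and 1906 lower, and 5559 had an unadjusted p below 0.05. The tests on counts and on TPM held 13 libraries, with 1 for T47D in low glucose. The edgeR test called 2387 (1191 higher, 1196 lower) and limma on TPM 1714. Leaving out a T47D glucose library gave 2367 (low-glucose replicate 1), 2122 (low-glucose replicate 2), 2166 (high-glucose replicate 1) or 2450 (high-glucose replicate 2). Further genes with the largest increases were the inducible chaperone HSPA6 (log2 fold change 4.13), the metallothioneins MT1F (4.01) and MT1X (3.29), LAMP3 (3.81, 18.4-fold), GPNMB (3.69), the stress cytokine GDF15 (3.22), RENBP (2.89) and FGF12 (2.81). Next to TXNIP and RRM2, the largest decreases were FAM111B (−2.60), the DNA methylation cofactor UHRF1 (−2.56), MYBL2 (−2.52), the replication factor MCM10 (−2.51), PGLYRP2 (−2.50), NMU (−2.48), the readthrough gene CENPS-CORT (−2.47, adjusted p = 0.0912 by edgeR) and the cyclin CCNE2 (−2.46). SPC25 (−2.65) was left out of these, as that identifier is not in GENCODE 29, and at the one that is SPC25 was not called (−0.60, adjusted p = 0.105). Metallothioneins, HSPA6, histones, ribosomal proteins, readthrough genes and 5S rRNA pseudogenes share sequence with near copies, so their values are uncertain.

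Genes of cell division fell together in T47D. All 34 measured genes of DNA replication were lower (34 adjusted over the list alone), with a median log2 fold change of −1.95, and MCM7 (−1.73), MCM5 (−2.42) and E2F1 (−2.12) among them. All 30 mitotic genes were lower (30 adjusted over the list alone, median −1.88), including CDC20 (−1.62), BIRC5 (−1.98) and UBE2C (−1.88). Camera gave adjusted p of 9.18e-32 and 1.93e-27 for these lists, and 0.127 and 0.192 at an estimated correlation. The proliferation marker MKI67 fell from 14.1 ± 1.62 to 4.23 ± 0.85 (−1.54, adjusted p = 0.000172) and the cyclin CCND1 by 1.48 on the log2 scale, while the cell cycle inhibitor CDKN1A was at 24.8 ± 0.87 against 25.9 ± 3.26 (adjusted p = 0.901). Of 27 estrogen receptor genes 14 were lower and 1 higher (15 and 1 adjusted over the list alone), with PDZK1 (−2.20), PGR (−0.95) and FKBP4 (−0.90) among them. The median was −0.44 with an adjusted p of 0.000109, or 0.473 at an estimated correlation. ESR1 itself was lower (−0.78), but not without high-glucose replicate 2 (−0.58, adjusted p = 0.0600) and not in limma on TPM (adjusted p = 0.0536).

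Of the stress lists, 4 lay above the other genes in T47D and heat shock did not. In the unfolded protein response 21 of 25 genes were higher and 0 lower (21 adjusted over the list alone, median 1.24), with ERN1 (1.62) and HYOU1 (1.83) among them. Of 28 ATF4 targets 18 were higher and 1 lower (20 and 1 adjusted over the list alone, median 0.81). TRIB3 (2.30), SLC3A2 (2.59) and CEBPG (1.16) were among the higher ones, while ASNS was at 56.8 ± 5.50 against 51.4 ± 5.28 (adjusted p = 0.411). In the oxidative stress response of NRF2, 11 of 19 genes were higher and 0 lower (12 adjusted over the list alone, median 0.86), among them FTL (2.06), NQO1 (1.60) and HMOX1 (2.72). Of 29 autophagy and lysosome genes 22 were higher and 0 lower (25 and 1 adjusted over the list alone, median 0.60), with CTSA (1.47), RRAGD (2.31) and MCOLN1 (1.38). Camera gave adjusted p of 4.68e-15, 4.45e-09, 1.65e-07 and 2.75e-11 for these 4 lists. At an estimated correlation the NRF2 list alone of the 16 lists called in T47D held, with an adjusted p of 0.0185, and the other 3 had 0.162, 0.215 and 0.127. Of 15 heat shock genes 0 were higher and 4 lower (1 and 5 adjusted over the list alone, median −0.20), the lower ones being FKBP4, HSP90AA1 (−0.70), STIP1 (−0.44) and DNAJA1 (−0.43), and the list did not pass (adjusted p = 0.152, or 0.627 at an estimated correlation). STIP1 lost its call without any 1 T47D glucose library (adjusted p = 0.0502 to 0.0747). DNAJA1 lost it without T47D low-glucose replicate 2 (0.255), T47D high-glucose replicate 1 (0.195) or 2 (0.0920), or any 1 T47D library at 10 or 25 mM (0.0504 to 0.0514).

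Metabolic groups moved in both directions. Of 24 cholesterol genes 12 were higher and 1 lower (14 and 1 adjusted over the list alone, median 0.49), with SQLE (1.01), LSS (1.06) and HMGCR (1.02), at a camera adjusted p of 5.57e-06 (0.337 at an estimated correlation). Of 19 hypoxia targets 11 were higher and 1 lower (the same counts adjusted over the list alone, median 0.47), with VEGFA (1.27) and NDRG1 (1.55), and of 20 FOXO targets 10 were higher and 0 lower (10 adjusted over the list alone, median 0.43), with KLHL24 (1.55) and CCNG2 (1.32). The adjusted p of these lists were 0.000430 and 5.97e-05, and 0.127 and 0.229 at an estimated correlation. Of 19 fatty acid oxidation genes 7 were lower and 1 higher (8 and 2 adjusted over the list alone, median −0.27), with ACAA2 (−0.82) and HADH (−0.77), at an adjusted p of 0.00651 (0.286 at an estimated correlation). Of 20 glycolysis genes 3 were higher and 6 lower (4 and 8 adjusted over the list alone) and the list did not pass (adjusted p = 0.152). Its genes went apart, with HK2 (1.83) and ALDOC (1.35) higher and LDHA (−1.11) and PGAM1 (−0.61) lower. The ketogenic enzyme HMGCS2 was lower (−1.38, adjusted p = 0.00140), and the ketone-using BDH1 (0.07) and OXCT1 (−0.10) and the transporter SLC16A1 (0.07) did not pass.

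Of the other lists called in T47D, 6 of 12 HDAC-inhibitor-responsive genes were higher (7 adjusted over the list alone, median 0.55, adjusted p = 0.00598), among them MT1F, MT1X and MT2A, which bind metals and respond to many stresses. Of 55 ribosomal proteins 19 were higher (22 adjusted over the list alone, median 0.28, adjusted p = 1.65e-07), with RPS28 (0.60), and of 24 interferon-stimulated genes 5 were lower and 2 higher (7 and 2 adjusted over the list alone, median −0.27, adjusted p = 0.0300), with OAS3 (−1.54) and ISG20 (0.93). The nuclear-encoded respiratory chain had 8 of 60 genes lower (2 adjusted over the list alone, median −0.20, adjusted p = 0.00252), whereas 2 of 13 mitochondrially encoded genes were higher (1 adjusted over the list alone, median 0.50, adjusted p = 0.0300). At an estimated correlation the adjusted p of these 5 lists were 0.229, 0.558, 0.627, 0.627 and 0.672. The nuclear-encoded list lost its call without high-glucose replicate 1 (−0.13), the mitochondrially encoded one without low-glucose replicate 1 (0.31) or high-glucose replicate 2 (0.29), and the interferon list without low-glucose replicate 1 (−0.25) or MCF-7 replicate 1 (−0.25) or 2 (−0.27) at 25 mM BHB. Markers of fibroblasts (0 of 7 higher, 2 lower, adjusted p = 0.170) and of basal and mesenchymal epithelium (0 of 7 called by limma or edgeR, adjusted p = 0.666) did not pass as lists.

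**Figure D3:**
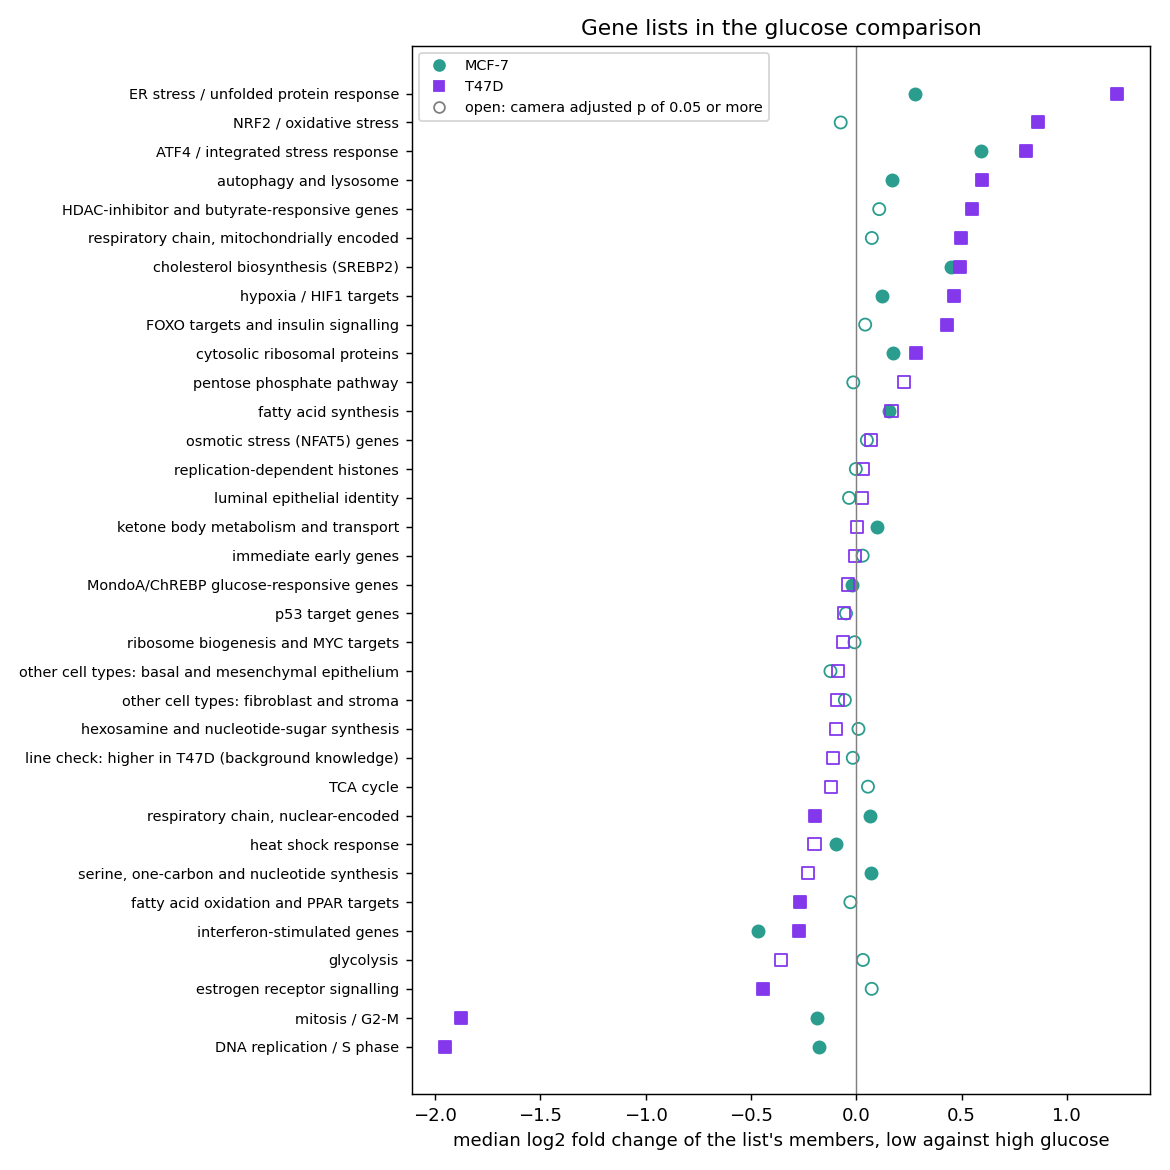
Median log2 fold change of each gene list in low against high glucose, with MCF-7 as circles and T47D as squares. Open symbols mark lists with a camera adjusted p of 0.05 or more. DNA replication and mitosis lie near −1.95 and −1.88 in T47D and near −0.18 and −0.19 in MCF-7.

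As the mean of both lines, low glucose lowered TXNIP (−3.56 ± 0.16, adjusted p = 2.67e-06) and raised NUPR1 (1.74), TRIB3 (1.45), SLC3A2 (1.66), GDF15 (1.92) and RRAGD (1.66). Of these, TRIB3, SLC3A2, GDF15 and RRAGD were not called in MCF-7 alone. The change of TRIB3 was 0.61 in MCF-7 and 2.30 in T47D. Of 28 ATF4 targets 22 were higher (24 adjusted over the list alone, median 0.71), and of 24 cholesterol genes 17 (21 adjusted over the list alone, median 0.43), with adjusted p of 2.36e-16 and 3.70e-12, or 0.0945 and 0.126 at an estimated correlation. Interferon-stimulated genes had 7 of 24 lower and 1 higher (12 and 1 adjusted over the list alone, median −0.39, adjusted p = 3.09e-05), or 0.267 at an estimated correlation. Heat shock genes had 4 of 15 lower and 0 higher (4 and 0 adjusted over the list alone, median −0.15, adjusted p = 0.0419, or 0.526 at an estimated correlation). That call was lost without MCF-7 high-glucose replicate 1 (−0.13), MCF-7 low-glucose replicate 2 (−0.06), T47D high-glucose replicate 1 (−0.16), T47D low-glucose replicate 2 (−0.13) or T47D replicate 1 or 2 at 10 mM (−0.15 for each). The mean called 2466 genes (1254 higher, 1212 lower), with 1502 by edgeR and 959 by limma on TPM. Leaving out an MCF-7 library at 25 mM BHB gave 3742 (replicate 1) or 3733 (replicate 2), T47D high-glucose replicate 1 1628, and T47D low-glucose replicate 2 1512. Across the 15447 genes the fold changes of the lines correlated at r = 0.25 (rho = 0.26), with genes not being independent replicates. Called in both lines were 5 higher and 1 lower genes, where independent lists would share 1.10 and 0.617. Without MCF-7 replicate 1 at 25 mM BHB these were 25 and 2, where independent lists would share 6.10 and 0.997.

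The difference between the lines was tested directly. The response of LCN2 was higher in T47D by 4.87 ± 0.29 on the log2 scale (adjusted p = 5.45e-05), of HSPA6 by 4.07, LAMP3 by 3.94, MT1F by 3.74 and MT1X by 2.86. The responses of PDZK1 (−2.74), NMU (−2.64), RRM2 (−2.62) and FAM111B (−2.50) were lower in T47D, and none of these 4 genes was called in MCF-7. The response of ASNS (−1.17) was also lower and that of ARRDC4 (1.47) higher in T47D, where neither gene was called. For TXNIP the difference of 0.46 did not pass (adjusted p = 0.458). In DNA replication 33 of 34 genes differed (34 adjusted over the list alone, median −1.84), in mitosis 30 of 30 (30 adjusted over the list alone, −1.68), in the unfolded protein response 16 of 25 (19 adjusted over the list alone, 1.01) and in the NRF2 response 8 of 19 (12 adjusted over the list alone, 0.86). At an estimated correlation the NRF2 list held (adjusted p = 0.00802), and the other 3 had 0.173, 0.241 and 0.241. Cholesterol genes did not differ as a list (median 0.07, adjusted p = 0.699). In all 1279 genes differed, 549 with a higher and 730 with a lower response in T47D, against 478 by edgeR, 764 by DESeq2 and 316 by limma on TPM. The count was 738 and 837 without MCF-7 low-glucose replicate 1 and 2, 710 without MCF-7 high-glucose replicate 1, 2265 and 2254 without MCF-7 replicate 1 and 2 at 25 mM BHB, 818 and 669 without T47D low-glucose replicate 1 and 2, and 659 without T47D high-glucose replicate 1. It was 2118 with the MCF-7 library of 2 stated doses set to 10 mM.

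The next question was whether BHB changes the low-glucose state. At 10 mM in MCF-7 there was 1 library, set against a spread taken from the other groups, so its gene and list values cannot separate BHB from that library's own deviation. On this footing 3 genes passed and none was protein-coding. They were RNA5SP61 (2.47 ± 0.27 without BHB and listed at 0 with it), AL157834.3 (listed at 0 without BHB and at 2.16 with it) and AC009412.1 (7.90 ± 3.86 and 0.51), all outside the naming rule and chosen after their values were seen. Without low-glucose replicate 1, RNA5SP61 and AL157834.3 (adjusted p = 0.0553) did not pass, nor did AL157834.3 without replicate 2 (0.0585). Among named protein-coding genes the smallest p belonged to ANO7 (log2 value −1.11), TCF4 (1.38), LCN2 (−1.33), DMGDH (−1.10) and NUPR1 (−1.09), each with an adjusted p of 0.415. PBX2 (1.72, adjusted p = 0.334) was left out, as that identifier is not in GENCODE 29. Camera called 9 lists and 0 at an estimated correlation. Among these, cholesterol genes (0 of 24 called, median −0.12) had an adjusted p of 0.00699 (0.845 at an estimated correlation), lost without MCF-7 low-glucose replicate 1 (−0.02). The unadjusted count was 385 in limma, and edgeR, which did not test the 3 genes that passed, called 0 genes (241 unadjusted). The count was 5 without MCF-7 replicate 1 at 25 mM BHB, without MCF-7 high-glucose replicate 1 or without T47D high-glucose replicate 2, 156 with no filter and 11 in a fit on only the libraries compared.

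At 10 mM in T47D 4 genes were called, none protein-coding, all chosen after their values were seen. RNA5SP61 (2.68 ± 0.47), RNA5SP301 (2.05 ± 0.38) and NCOR1P4 (2.23 ± 0.69) were listed at 0 without BHB, and RNA5SP263 was listed at 0 with it (4.01 ± 2.75 without). The RNA5SP263 call was lost without any 1 of 12 libraries, namely the MCF-7 libraries at 0 or 25 mM or in high glucose and the T47D libraries at 10 or 25 mM or in high glucose (adjusted p = 0.0651 to 0.383). NCOR1P4 lost its call without T47D low-glucose replicate 1 (0.0986) or 2 (0.0558) or T47D replicate 1 at 10 mM (0.0557), and RNA5SP301 without T47D low-glucose replicate 1 (0.0525). The named genes with the smallest p were VARS2 (−0.75), RBP4 (0.76), KCNQ5 (0.70), PLEKHG2 (0.49) and SPATA1 (−1.07), at adjusted p of 0.606 to 0.815. A second VARS2 identifier (0.71, adjusted p = 0.400), SERF1A (1.16) and UTP4 (−2.64) were left out, as these identifiers are not in GENCODE 29, and the 2 VARS2 values went apart. Camera called 3 lists and 0 at an estimated correlation. Cholesterol genes (0 of 24 called by limma or edgeR, median −0.12, adjusted p = 0.0190, or 0.992 at an estimated correlation) lost the call without T47D replicate 1 at 10 mM (−0.02) or T47D low-glucose replicate 2 (−0.04). The unadjusted count was 357, and edgeR, which did not test the 4 called genes, called 0 (192 unadjusted). The limma count was 1 without T47D low-glucose replicate 1 and 24 with no filter.

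At 25 mM in MCF-7 the 5S rRNA pseudogenes RNA5SP61 (listed at 0, against 2.47 ± 0.27 without BHB), RNA5SP160 (3.26 ± 0.80 against 0) and RNA5SP448 (1.85 ± 0.49 against 0) were called, again chosen after their values were seen. RNA5SP160 and RNA5SP448 lost their calls without low-glucose replicate 1 (adjusted p = 0.0513 for each) or 2 (0.0904 for each), and RNA5SP160 without replicate 1 at 25 mM (0.0662). No protein-coding gene was called by limma, with 1161 genes at an unadjusted p below 0.05. The edgeR test, which left out the called pseudogenes, called 0 genes (1021 unadjusted). HMGCS1, an early enzyme of the cholesterol pathway, had the smallest p among named genes, at 38.6 ± 2.65 FPKM with BHB and 63.4 ± 2.84 without (log2 value −0.70 ± 0.11, adjusted p = 0.173), followed by BNIPL (0.52), TFRC (−0.53), NFATC4 (0.84) and CATSPER2 (0.84). Camera called 10 lists and 0 at an estimated correlation. Cholesterol genes (0 of 24 called over all genes, 3 lower adjusted over the list alone, median −0.31) had an adjusted p of 3.20e-11, or 0.388 at an estimated correlation. All 20 glycolysis genes had negative values (0 called, median −0.23, adjusted p = 3.51e-05, or 0.506 at an estimated correlation) and all 13 mitochondrially encoded genes positive ones (0 called, median 0.47, adjusted p = 0.000175, or 0.656), and both calls were lost without replicate 1 at 25 mM, with medians of −0.02 and −0.07. The number of called genes was 2545 without replicate 2 at 25 mM, 1 without low-glucose replicate 2, 5 without either MCF-7 high-glucose replicate, 29 with no filter and 14 in DESeq2. The characteristics of replicate 2 state 10 mM, and with it set to 10 mM, 2187 genes were called, replicate 1 then being the 25 mM group alone.

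At 25 mM in T47D 4 genes outside the naming rule were called, none protein-coding. RNA5SP301 (2.31 ± 0.38) and AL603910.2 (1.79 ± 0.24) were listed at 0 without BHB, FAM27B was at 5.32 ± 0.29 against 1.26 ± 0.04, and RNA5SP263 was listed at 0 with BHB. All were chosen after their values were seen. FAM27B lost its call without any 1 MCF-7 library at 0 or 25 mM or in high glucose or any 1 T47D library at 0 or 25 mM (adjusted p = 0.0581 to 0.414). RNA5SP263 lost it without any 1 of the same MCF-7 libraries, any 1 T47D library at 10 or 25 mM, or T47D high-glucose replicate 2 (0.0502 to 0.414). Named genes with the smallest p were NME4 (0.58), PLEKHG2 (0.73), NCF2 (−0.94), HSPA6 (−1.11) and MS4A15 (1.06), at adjusted p of 0.0628 to 0.168. VARS2 was left out, with a smaller p than NME4 (0.88, adjusted p = 0.0628) at an identifier not in GENCODE 29, and went the other way at the one that is (−0.80, adjusted p = 0.223). Camera called 7 lists and 0 at an estimated correlation. All 24 cholesterol genes had negative values (0 called, median −0.26, adjusted p = 9.49e-08, or 0.674 at an estimated correlation), and 17 of 19 NRF2 genes did (0 called, median −0.24, adjusted p = 0.000272, or 0.0762). The unadjusted count was 809, and edgeR called 0 genes (500 unadjusted), having tested FAM27B alone of those called by limma. Called genes numbered 2 without MCF-7 low-glucose replicate 1 or 2 or T47D replicate 2 at 25 mM, 7 without T47D replicate 1 at 25 mM, 9 without T47D high-glucose replicate 1, 8 without T47D low-glucose replicate 2, 29 with no filter and 7 with the MCF-7 library of 2 stated doses set to 10 mM.

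As the mean of both lines, limma called 2 named genes higher with 25 mM BHB, neither of which was called within a line. They were PLEKHG2, a Rho exchange factor (0.66 ± 0.08, adjusted p = 0.0261), and NME4, a mitochondrial nucleoside diphosphate kinase (0.47 ± 0.06, adjusted p = 0.0308). PLEKHG2 lies on chromosome 19 at 39412585 to 39428415 and NME4 on chromosome 16 at 396725 to 410367. In T47D NME4 was at 92.5 ± 0.50 with 25 mM BHB and 61.5 ± 0.07 without. HMGCS1 was at 41.9 ± 3.75 and 50.3 ± 2.81 there, and its mean change of −0.48 ± 0.08 did not pass (adjusted p = 0.0892). Of the other 5 of 7 called genes, all chosen after their values were seen, RNA5SP61 was lower and RNA5SP301, RNA5SP160, RNA5SP448 and AL603910.2 were higher. The unadjusted count was 1274, edgeR called 0 genes (849 unadjusted, adjusted p = 0.755 for PLEKHG2 and NME4) and DESeq2 called 14. Of the 7 genes called by limma, edgeR tested PLEKHG2 and NME4 alone. The PLEKHG2 call was lost without MCF-7 low-glucose replicate 1 (adjusted p = 0.108) or 2 (0.224), MCF-7 replicate 1 at 25 mM (0.0644), T47D low-glucose replicate 1 (0.128) or 2 (0.0806), or T47D replicate 1 (0.157) or 2 (0.153) at 25 mM. The NME4 call was lost without each of these (0.114, 0.244, 0.0644, 0.180, 0.0993, 0.173 and 0.205 in the same order) and without T47D replicate 1 (0.0515) or 2 (0.0542) at 10 mM. The count was 1318 without MCF-7 replicate 2 at 25 mM, 1 without replicate 1 there, 0 without either low-glucose replicate of MCF-7 or T47D or T47D replicate 1 at 25 mM, 1 without T47D replicate 2 at 25 mM, and 4 without either T47D replicate at 10 mM. With MCF-7 replicate 2 set to 10 mM it was 1037, and with no filter 32.

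Cholesterol genes had the smallest camera p among the 13 lists called at 25 mM over both lines. All 24 had negative values (median −0.30, adjusted p = 1.86e-14), none was called over all genes and 14 were lower when adjusted over the list alone, with an adjusted p of 0.175 at an estimated correlation. At 10 mM the median was −0.12 (adjusted p = 0.000322, or 0.910 at an estimated correlation), a call lost without T47D replicate 1 at 10 mM (−0.10) or T47D low-glucose replicate 2 (−0.09). Between 25 and 10 mM it was −0.16 (adjusted p = 1.83e-08, or 0.645). Also below the other genes at 25 mM were heat shock genes (0 of 15 called, 4 lower adjusted over the list alone, median −0.18), hypoxia targets (0 of 19, 0 adjusted over the list alone, −0.15), NRF2 genes (0 of 19, 2 adjusted over the list alone, −0.10) and fatty acid synthesis genes (0 of 15, 2 adjusted over the list alone, −0.13). Their adjusted p were 0.000232, 0.00265, 0.00395 and 0.00476, and 0.380, 0.175, 0.175 and 0.175 at an estimated correlation. Glycolysis genes (0 of 20, 1 lower adjusted over the list alone, −0.19) had an adjusted p of 0.000188, or 0.515 at an estimated correlation, lost without MCF-7 replicate 1 at 25 mM (−0.06). Replication-dependent histones (0 of 16 called, 2 higher adjusted over the list alone, 0.10) had 0.00265, or 0.279. HDAC-inhibitor-responsive genes were not among the lists called, and H1-0 had a log2 value of −0.08.

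**Figure D4:**
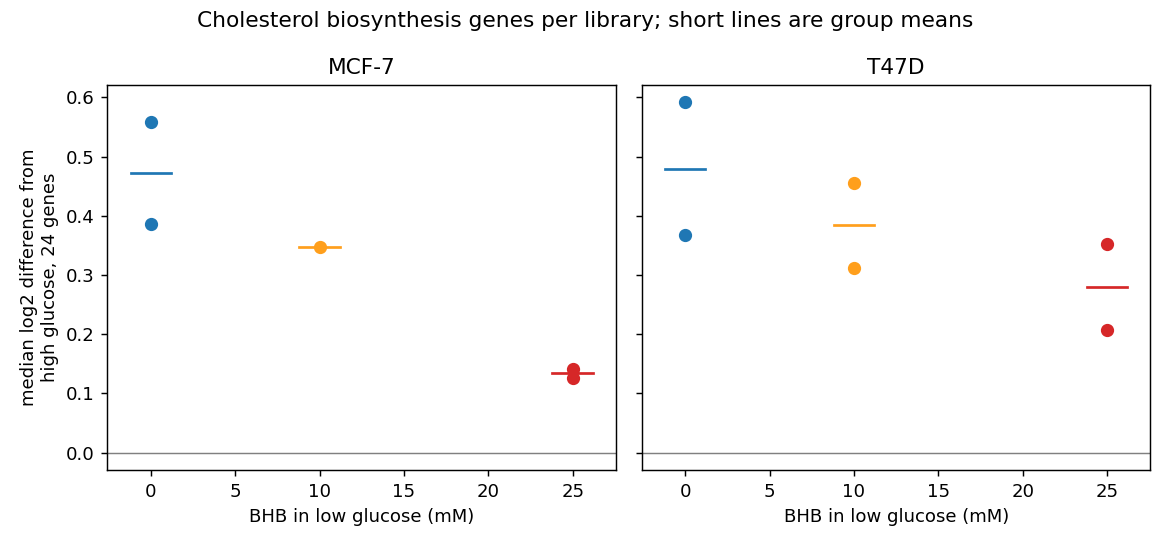
Median log2 difference from the high-glucose mean of the 24 cholesterol biosynthesis genes against BHB in mM, with 1 point per low-glucose library and 1 panel per cell line. MCF-7 libraries lie at 0.56 and 0.39 without BHB, 0.35 at 10 mM and 0.14 and 0.13 at 25 mM, and T47D libraries at 0.37 and 0.59, 0.31 and 0.46, and 0.21 and 0.35.

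Over both lines 10 mM BHB gave 0 called genes in limma (405 unadjusted) and edgeR (280 unadjusted), and 2 in DESeq2. In limma 405 lay below the 772 that chance alone would give, as did 385 in MCF-7 and 357 in T47D at 10 mM. The counts of 469 for 25 against 10 mM and 636 for the line difference in BHB did so too. Few calls in these comparisons thus do not show that BHB changed nothing. DMGDH (−0.67), LCN2 (−0.78), ACAP1 (−0.73), ZNF705A (−0.79) and NUPR1 (−0.57) had the smallest p among named genes, at adjusted p of 0.795 or more. PBX2 was left out with 2 identifiers not in GENCODE 29 that went apart (−0.68, adjusted p = 0.121, and 0.88, adjusted p = 0.960). The count was 1 without MCF-7 low-glucose replicate 1, T47D high-glucose replicate 1 or 2, or T47D replicate 2 at 25 mM, and 2 without T47D replicate 1 at 10 mM. Between 25 and 10 mM, AC009412.1 (1.56) and RNA5SP61 (−0.94) were called, both chosen after their values were seen, with 469 genes unadjusted and 0 in edgeR (382 unadjusted) and DESeq2. Neither of these 2 genes was tested by edgeR. PLEKHG2 (0.50) had the smallest p among named genes (adjusted p = 0.286). AC009412.1 lost its call without MCF-7 replicate 1 at 25 mM (adjusted p = 0.107), MCF-7 high-glucose replicate 2 (0.0551), or T47D replicate 1 (0.113) or 2 (0.180) at 10 mM or 1 (0.102) or 2 (0.212) at 25 mM. RNA5SP61 lost it without each of these (0.107, 0.0551, 0.0582, 0.180, 0.102 and 0.212 in the same order) and without MCF-7 low-glucose replicate 1 (0.0615) or 2 (0.0644). This count was 0 without T47D replicate 1 or 2 at 25 mM or replicate 2 at 10 mM, 1 without MCF-7 replicate 1 at 25 mM, MCF-7 high-glucose replicate 2 or T47D replicate 1 at 10 mM, 7 without MCF-7 replicate 2 at 25 mM, 5 without MCF-7 high-glucose replicate 1 or either T47D high-glucose replicate, 4 without either T47D low-glucose replicate, 106 with the MCF-7 library of 2 stated doses set to 10 mM and 110 with no filter.

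The lines' responses to 25 mM BHB differed in 2 genes, RNA5SP61 (1.79) and RNA5SP301 (1.72), both chosen after their values were seen, with 636 genes unadjusted and 0 in edgeR (509 unadjusted). Neither gene was tested by edgeR. The named genes with the smallest p were BNIPL (−0.78, adjusted p = 0.108), TGIF2-RAB5IF (1.32), TGFBR3L (0.84), IKBKG (−0.69) and LRP4 (0.94). Camera called 4 lists and 0 at an estimated correlation. The count was 406 without MCF-7 replicate 2 at 25 mM, 6 without either T47D high-glucose replicate, 1 without T47D replicate 2 at 25 mM, and 0 without MCF-7 replicate 1 at 25 mM, any MCF-7 glucose library, or T47D replicate 1 in low glucose or at 25 mM. With the MCF-7 library of 2 stated doses set to 10 mM it was 177, and with no filter 28.

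Whether BHB moved genes back toward their high-glucose level was compared through the correlation across genes of the 25 mM BHB and low-glucose fold changes, genes not being independent replicates. It was −0.39 in MCF-7 and −0.37 in T47D. Both fold changes use the same low-glucose libraries, and simulated unchanged groups gave −0.50 in each line. The covariance was −0.0211 in MCF-7 against a simulated −0.0207, and −0.0425 in T47D against −0.0207, a difference of −0.0218 in T47D. With each fold change set against a different low-glucose library, r was 0.07 and −0.07 in MCF-7 and −0.22 and −0.09 in T47D, and as single libraries then stand for the low-glucose group, their own deviations enter these values. Over the 14 genes called for glucose in MCF-7, r was −0.37, or −0.27 and −0.43 with no shared library, and 78.6% moved opposite to the glucose change. Over the 3798 called in T47D, r was −0.50, or −0.53 and −0.28, and 71.0% moved opposite. Simulated with the observed glucose changes as true and no BHB effect, called genes gave r of −0.21 with a simulated SD of 0.285 in MCF-7 and −0.24 with an SD of 0.0189 in T47D. With no shared library the simulated r was −0.16 in MCF-7 and −0.12 in T47D, and 59.3% and 59.6% moved opposite with shared libraries. The simulated noise was drawn independently for each gene, so its SDs leave out genes that move together within a library. In T47D the values of −0.53 and −0.28 with no shared library lay further apart than the simulated SD of 0.0203 would give. The simulation thus cannot show whether BHB moved genes back.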

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

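The tests of the slope, the TXNIP ratio, the depth ratio, the best correlation with any other library, the T47D median, the change from 10 to 25 mM BHB and the estimated correlation were chosen only after the results were seen, while the splits, the mitochondrial genes, the BHB response and the library left out were chosen before.

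The lines differed in their response to low glucose in 1279 genes by the test of the difference itself. The response of LCN2 was higher in T47D by 4.87 on the log2 scale, of HSPA6 by 4.07, LAMP3 by 3.94, MT1F by 3.74, MT1X by 2.86, DDIT3 by 2.27, HSPA5 by 1.79, TRIB3 by 1.69, MT2A by 1.62, ARRDC4 by 1.47 and HK2 by 1.31. It was lower by the same test for PIGY (−3.91), PDZK1 (−2.74), NMU (−2.64), RRM2 (−2.62), FAM111B (−2.50), CCND1 (−1.39), MKI67 (−1.36), HMGCS2 (−1.35), ASNS (−1.17) and PGR (−0.87). These differences are signed, and ARRDC4 was lowered less in T47D (−0.40, not called) than in MCF-7 (−1.87). PIGY was called in neither line (2.47 in MCF-7, adjusted p = 0.424, and −1.44 in T47D, adjusted p = 0.152). HMGCS2 was at 0 to 0.069 FPKM in all MCF-7 libraries, so its difference comes from T47D alone. The line difference in the 25 mM BHB response covered 2 genes, RNA5SP61 (1.79) and RNA5SP301 (1.72), which are listed at 0 in some groups.

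Some of these differences lost their call without 1 library. Without MCF-7 high-glucose replicate 1, MCF-7 low-glucose replicate 2, T47D high-glucose replicate 1 and T47D low-glucose replicate 2 in turn, the adjusted p was 0.116, 0.104, 0.0637 and 0.119 for PIGY, 0.0936, 0.0653, 0.0760 and 0.0883 for DDIT3, and 0.0627, 0.0544, 0.0631 and 0.0515 for CCND1. PIGY (0.0997) and DDIT3 (0.0612) also lost it without T47D high-glucose replicate 2, and PGR (0.0530) and MT2A (0.0566) without T47D low-glucose replicate 2. In edgeR on 13 libraries these 5 and HMGCS2 were not called, with adjusted p of 0.157 for PIGY, 0.156 for DDIT3, 0.187 for CCND1, 0.338 for PGR, 0.0561 for MT2A and 0.939 for HMGCS2, whose log2 value turned to 0.48. HMGCS2 lost it without any 1 of the 8 glucose libraries but T47D high-glucose replicate 1, with adjusted p of 0.0627 or more. RNA5SP61 and RNA5SP301 lost theirs without any 1 low-glucose library or 25 mM library of either line, except MCF-7 replicate 2 at 25 mM, and without either MCF-7 high-glucose replicate, with adjusted p of 0.0651 to 0.244.

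The first pattern weighed is the larger number of genes called in T47D than in MCF-7. If more spread in MCF-7 hid changes of the same size, MCF-7 fold changes would follow those of T47D with a slope near 1. Over the genes called in T47D, which were picked by their T47D change, the slope was 0.11. The fit also shared 1 spread per gene, with the same standard error in both lines (0.205 for LCN2 in each). More spread in MCF-7 alone thus could not lower its calls below those of T47D. A shared medium in the MCF-7 libraries is argued against by TXNIP, whose log2 fold change in MCF-7 was 1.14 times that in T47D, and a lower depth by a mean depth 1.23 times that of T47D. A difference between the cell lines themselves, which the design names, may underlie the pattern and stays open as a hypothesis. Among 34 splits of the 8 glucose libraries over both lines, with cell line as a term, the real one called 21 genes and the highest other 2. Only the real split was as large, a share of 2.94%, the smallest that 34 splits can give. This argues against a chance split of these libraries, whose replicates may be technical, and does not exclude chance. These fits used the 8 libraries alone and 1 glucose effect common to both lines, so differences between the lines' responses entered the spread. The fit on all 15 libraries, which called 2466, had 1 mean per group, so the 2 counts differ by model as well as by libraries.

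The second pattern is the MCF-7 library with 25 mM BHB, replicate 1, that stood apart. Without mitochondrially encoded genes its correlation with its replicate was 0.977, still below the lowest other replicate pair at 0.990. These genes are few among those tested, and rescaling the rest hardly alters a correlation of log2 values. With them the correlation was 0.978, so this test could hardly come out otherwise and cannot decide on these genes. The best correlation of this library with any other was 0.986, with MCF-7 at 10 mM, below the lowest best correlation of the others at 0.990. That argues against a swap within the series as the whole source. A swapped library that also deviated would give the same value, so a swap of this library was not excluded. A fuller BHB response cannot be told apart, since its correlation with the T47D response was 0.068, but the bound of 0.1 set before could not separate the libraries, the other one at 25 mM lying below it too at 0.095. The state of the culture or of the RNA was not tested.

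The third pattern is the lower cholesterol biosynthesis list at 25 mM BHB. The library that stood apart is argued against as the whole source of the fall by T47D, whose means it does not enter. There the median was −0.26 with a standard error of 0.103. For MCF-7 this library cannot be told apart, since without it the median of −0.36 rested on 1 library. The characteristics of that remaining library state 10 mM, while its title and column header give 25 mM. Chance values of the shared low-glucose libraries cannot be told apart, as the median from 10 to 25 mM, which uses none of them, was −0.16 with a standard error of 0.0811. Members that move together between libraries may account for the small camera p, as the adjusted p was 0.175 with an estimated correlation, so the change stays a hypothesis. Chance could not be excluded for the counts of called genes at 25 mM BHB (real 1, highest other 2, 5 of 34 splits as large, the real one included) or between 25 and 10 mM (real 1, highest other 12, 9 of 34), in fits on the compared libraries alone, while at 10 mM the real count of 0 left all 34 of 34 splits as large (highest other 12), so that test could not come out otherwise.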

How the results depend on the processing

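Chosen only after the data were seen were edgeR on 15 libraries with 2 rebuilt, genes with at least 10 mean estimated counts, protein-coding genes alone and the agreement between lines without 1 library, and the other alternatives were fixed before. Of 21664 alternative values of 689 results for single genes, 19688 kept their direction and side of the threshold, 1392 lost the call, 179 gained one, 4 turned around and 401 changed sign with no call on either side. Of 8046 values of 408 list results these counts were 7205, 275, 198, 30 and 338. Genes with few reads are the least precise, and 2 reference libraries entered through FPKM alone. Where leaving out a library left an arm with 1 sample, that sample was assumed to vary like the other groups. The MCF-7 10 mM comparisons could not be given without their lone library. Except where stated, the cause was not tested.

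Over the libraries left out in turn, called genes ranged from 8 to 43 in MCF-7 glucose, 2122 to 5085 in T47D glucose, 1512 to 3742 for both lines' glucose response and 659 to 2265 for the line difference in it. For BHB they ranged from 2 to 5 in MCF-7 and 1 to 5 in T47D at 10 mM, 1 to 2545 in MCF-7 and 2 to 9 in T47D at 25 mM, and over both lines 0 to 2 at 10 mM, 0 to 1318 at 25 mM and 0 to 7 for 25 against 10 mM, with 0 to 406 for the line difference. Lists called ranged, in the same order, over 13 to 16, 14 to 16, 15 to 18, 11 to 15, 5 to 10, 1 to 7, 9 to 16, 6 to 14, 2 to 9, 11 to 18, 9 to 12 and 2 to 8. The highest glucose counts came without either MCF-7 library at 25 mM BHB (43 and 43 in MCF-7, 5085 and 5085 in T47D, 3742 and 3733 for both lines, 2265 and 2254 for the line difference, without replicate 1 and 2), as the divergent pair then no longer entered the shared spread. The counts of 2545, 1318 and 406 came only without replicate 2 there, when the library that stood apart was the whole MCF-7 group at 25 mM, and were 2, 1 and 0 without replicate 1. The agreement between the lines was 0.25 without replicate 1 of that pair and 0.31 with a filter of 5 FPKM.

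With an estimated correlation the lists called were 1 in T47D glucose, 1 for both lines' glucose response, 1 for the line difference in it and 0 in MCF-7 glucose and every BHB comparison. Fry called 5 in MCF-7 glucose, 20 in T47D glucose, 17 for both lines' glucose response and 12 for the line difference in it. For BHB it called 1 in T47D at 25 mM, 4 over both lines at 25 mM and 0 in the other comparisons. Camera on log2 CPM of 13 libraries called 6 lists in T47D at 10 mM and 7 for the line difference in BHB, where no filter gave 1 list and a filter of 5 FPKM 7.

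A pseudocount of 0.1 called 5 genes in MCF-7 at 10 mM, 8 in T47D at 25 mM, 2 over both lines at 10 mM, 4 for 25 against 10 mM and 4 for the line difference in BHB. No filter called 53 genes in MCF-7 glucose, 156 in MCF-7 and 24 in T47D at 10 mM, 29 in MCF-7 and 29 in T47D at 25 mM, 107 and 32 over both lines at 10 and 25 mM, 110 for 25 against 10 mM and 28 for the line difference in BHB. A filter of 5 FPKM called 1 in MCF-7 and 0 in T47D at 10 mM, 0 in each line and 2 over both lines at 25 mM, 1 for 25 against 10 mM and 0 for the line difference in BHB. Quantile normalisation called 0 for 25 against 10 mM and 1 for the line difference in BHB. A fit on only the libraries compared called 1 in MCF-7 glucose, 11 in MCF-7 and 2 in T47D at 10 mM, 1 in MCF-7 and 0 over both lines at 25 mM, and 0 for the line difference in BHB. No variance trend called 9 in T47D at 25 mM, 2 over both lines at 10 mM, 5 for 25 against 10 mM and 5 for the line difference in BHB.

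On counts of 13 libraries, edgeR called 4 genes in MCF-7 glucose, 2387 in T47D glucose, 1502 for both lines, 478 for the line difference and 0 in every BHB comparison. With the size factors of DESeq2 these were 4, 2407, 1506, 473 and 0. Without a filter edgeR called 128 in MCF-7 glucose, 45 in MCF-7 and 48 in T47D at 10 mM, 241 in MCF-7 and 66 in T47D at 25 mM, 58 and 109 over both lines at 10 and 25 mM, 45 for 25 against 10 mM and 95 for the line difference in BHB. DESeq2 called 39 in MCF-7 glucose, 2492 in T47D glucose, 764 for the line difference, 14 in MCF-7 and 14 over both lines at 25 mM, 2 over both lines at 10 mM and 0 for 25 against 10 mM. Limma on TPM called 9 in MCF-7 glucose, 1714 in T47D glucose, 959 for both lines, 316 for the line difference, 1 in T47D at 10 mM, 5 in MCF-7, 0 in T47D and 1 over both lines at 25 mM, and 0 for the line difference in BHB. On 15 libraries with 2 rebuilt, edgeR called 0 in each line at 10 and 25 mM, over both lines at 25 mM, for 25 against 10 mM and for the line difference in BHB. Genes with at least 10 mean counts gave 0 in each line at 10 and 25 mM, 2 over both lines at 25 mM and 0 for 25 against 10 mM and the line difference, and protein-coding genes gave 0, 2, 0 and 0 likewise.

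With the library of 2 stated doses set to 10 mM, the calls were 27 in MCF-7 glucose, 2187 in MCF-7, 7 in T47D and 1037 over both lines at 25 mM, 106 for 25 against 10 mM, 2118 for the line difference in glucose and 177 for that in BHB. The replicate block, taken from the series of sample numbers, called 37 in MCF-7 glucose, 0 for 25 against 10 mM and 1 for the line difference in BHB, and moved no other count of called genes by over 1.5 times. Libraries of the same number correlated in their deviations at −0.00 to 0.37, with 5 of 9 pairs above 0.1, and 12 of 15 libraries correlated best with a library of the same number. The labels name no batch, and not all 9 pairs passed 0.1, so the number entered as an alternative alone and a shared batch stays open. The correlation of the BHB with the low-glucose fold changes over all 15447 genes was −0.39 in MCF-7 and −0.37 in T47D, and with no shared library 0.072 and −0.068 in MCF-7 and −0.22 and −0.093 in T47D. Over the genes called for glucose it was −0.37 in MCF-7 and −0.50 in T47D, and with no shared library −0.27 and −0.43 in MCF-7 and −0.53 and −0.28 in T47D.

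HMGCS2 in the line difference turned from −1.35 to 0.48 with edgeR, 0.50 with the size factors of DESeq2, 0.50 without a filter and 0.76 with DESeq2. As HMGCS2 was at 0 to 0.069 FPKM in all MCF-7 libraries, its MCF-7 change in these tests rests on values at the floor. The direction of a list's test, which can differ from the sign of its median, turned in the following lists, given as the range of medians over the libraries left out. The turn came without MCF-7 replicate 1 at 25 mM, at the end of the range stated second, for the unfolded protein response (−0.35 to 0.077), estrogen receptor genes (−0.24 to 0.13) and luminal genes (−0.27 to 0.15) in MCF-7 at 25 mM, for the unfolded protein response (−0.14 to 0.099) and luminal genes (−0.12 to 0.084) over both lines at 25 mM, and in the line difference in BHB for the nuclear-encoded (−0.36 to 0.0097) and mitochondrially encoded (−1.10 to −0.011) respiratory chain and ribosomal proteins (−0.18 to 0.11). It came at the end stated first for the nuclear-encoded (−0.085 to 0.28) and mitochondrially encoded chain (−0.070 to 1.03) in MCF-7 at 25 mM, for the same 2 lists over both lines (−0.082 to 0.10 and −0.079 to 0.48), for mitochondrially encoded genes at 25 against 10 mM (−0.032 to 0.51) and for the unfolded protein response in the line difference (−0.061 to 0.36). Without MCF-7 replicate 2 at 25 mM, the turn came for ribosomal proteins in MCF-7 (−0.20 to 0.053) and over both lines (−0.16 to −0.017) at 25 mM and for the nuclear-encoded chain at 25 against 10 mM (−0.14 to 0.037), at the end stated second, and for luminal genes there (−0.084 to 0.11), at the end stated first.

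Without T47D replicate 1 at 10 mM, the turn came at the end stated first for DNA replication (−0.18 to 0.25) and mitosis (−0.28 to 0.27) in T47D at 10 mM and for the same 2 lists over both lines (−0.039 to 0.20 and −0.11 to 0.17). It came at the end stated second for cholesterol genes in T47D at 10 mM (−0.21 to −0.022) and for replication (−0.21 to 0.0080) and mitosis (−0.18 to 0.087) at 25 against 10 mM. Without T47D low-glucose replicate 2, cholesterol genes, replication and mitosis turned in T47D at 10 mM as well, at −0.041, −0.065 and −0.24, and mitosis turned at the end stated first at 25 mM in T47D (−0.20 to 0.24) and over both lines (−0.13 to 0.076).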

Other observations

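No test in this part was chosen only after the result was seen. In T47D in low glucose, p53 target genes went both ways, 5 of 24 being higher and 3 lower (5 and 3 adjusted over the list alone), with BBC3 (1.59) and TP53INP1 (1.13) higher and the death receptor FAS (−1.30) lower. Luminal identity genes did as well, with 5 of 16 higher and 2 lower (5 and 2 adjusted over the list alone), the mucin MUC1 (1.03) and the transcription factor ELF3 (1.72) being among the higher ones. Of 16 replication-dependent histone genes 4 were higher and 0 lower (4 adjusted over the list alone), with H4C8 (1.40) and H2BC21 (0.79). None of the 3 lists passed in camera, with adjusted p of 0.638, 0.536 and 0.281.

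In MCF-7 limma and edgeR called 0 genes of these 3 lists (1 luminal gene was higher when adjusted over the list alone), where limma gave 876 genes of all those tested an unadjusted p below 0.05.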
